A study of Mus musculus with 12 samples.

How the data were processed

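Kidneys of mice at postnatal day 18 were profiled for N6-methyladenosine (m6A), a methyl mark on messenger RNA, by immunoprecipitating RNA with an antibody against m6A and sequencing it beside the untreated input RNA. The labels describe 12 libraries from 3 genotypes: wildtype (WT), Pkd1F/RC-KO (single mutant, SKO) and Pkd1F/RC-Mettl3-DKO (double mutant, DKO). Each genotype has 2 m6A libraries and 2 input libraries. Replicate 1 is female and replicate 2 is male in every genotype, so the replicates come from separate animals and sex cannot be told apart from the replicate number. Per the labels' protocols, total RNA of frozen kidneys was precipitated with a commercial m6A kit, and libraries were made with a NEBNext Ultra RNA kit and read on an Illumina sequencer. That kit does not mark strand, so reads of a gene and of an antisense or overlapping partner cannot be told apart.

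The submitters' processing notes name STAR, MACS2 2.1.0, ChIPseeker, HOMER 4.7.2, edgeR, deepTools 3.1.1 and DiffBind with the mouse build mm10, and give no role or order for them. The table analysed here is named for DiffBind, a package that compares peak signal between groups of samples. It holds 133 rows, 1 per gene symbol, with a fold change, a p-value and a false discovery rate (FDR) for SKO against WT, DKO against WT and DKO against SKO. The authors deposited the fold changes without stating their scale. They behave as logarithms: SKO against WT plus DKO against SKO equals DKO against WT to within 0.03 in every row, and 103 of the DKO against WT values lie between -1 and 1, which a signed linear fold cannot. They are read here as log2 because that is the usual DiffBind output; the base itself is an assumption. The p-values and FDR values were deposited by the authors as they stand, and the test behind them, the normalization, and whether the input libraries entered it are not given in the sources used here. The fold and the p-value need not come from the same estimate: Klhl31 has a DKO against WT log2 fold of -0.01 with p = 0.669, and Cdkn2b has 0.01 with p = 0.972, both in the authors' deposited table.

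The table is a selected list. Every row has a positive SKO against WT fold with an FDR of at most 0.0924 and a negative DKO against SKO fold with an FDR of at most 0.0994. No row that changed in another way was analysed here. The directions of these 2 comparisons are therefore fixed by how the list was made and are not independent evidence of it, whereas DKO against WT was limited indirectly: it equals the sum of the other 2 differences, so it lies below the SKO rise in every row. The table holds no value per library, no signal level, no standard error and no peak position, so the spread between replicates is known only through the authors' p-values. Sequencing depth is unknown, and no counting interval or detection limit was given.

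The comparisons between genotypes rest on counts, medians and quartiles of the deposited values. The closing section adds Fisher's exact tests of marker lists, two-sided and Benjamini-Hochberg adjusted over the 9 lists, 10000 random gene sets, 1000 simulated tables without effects, and bounds on the number of tests. The only table analysed here came from 1 sheet of a workbook. Before the data were examined, an FDR of 0.05 was set as the threshold, and 9 pathway lists with 176 distinct genes and 9 cell type marker lists with 67 distinct genes were fixed. Also fixed then was the rule for naming genes: Pkd1, Mettl3, Myc and Avpr2, every listed member of those lists, and the 10 largest rises and 10 largest falls past the threshold in each comparison. Myc and Avpr2 were known from the study when the rule was written. The rule named 31 genes, of which 29 are in the table, and 1 of these is not reported here. The planned fits of counts or normalized values per library, the comparison of peak annotation classes and the enrichment of gene lists could not be fitted to a table of this kind. No new test between genotypes was made.

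Gene positions come from the RefSeq annotation of GRCm38.p6, the assembly that mm10 denotes, and are those of the gene, not of the peak. All 133 symbols were placed, 132 by their current symbol and 1 (Tmem173, now Sting1) by an older symbol. 2 rows have no Ensembl identifier. The authors' peaks carry a gene name and no position, so the transcript that carried a peak is uncertain for every gene. The uncertainty is greater for the 55 of the 133 genes that overlap another annotated gene.

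If the FDR values are Benjamini-Hochberg values, the ratio of FDR to p cannot exceed the number of tests, and that number times p over FDR gives the least number of tests with an FDR at or below it. Both were taken at the lower end of what rounding to 3 digits allows. Tested on simulated data, the least number of tests held in 20 of 20 simulated tables of about 133 genes per comparison, and 100% of the least counts were at or below the true ones. Because the fold and the p-value need not share an estimate, no standard error was derived from them. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Alternatives were an FDR of 0.01 or 0.1, minimum changes of 1.5-fold and 2-fold, leaving out Ddx18, and keeping only genes past FDR 0.05 in both selected comparisons.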

Results

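The study set m6A profiles of kidneys from WT mice against those of SKO and DKO mice. SKO mice carry mutant Pkd1, the gene most often mutated in autosomal dominant polycystic kidney disease. DKO mice are labelled as a knockout of Mettl3 as well, which encodes the catalytic subunit of the main m6A methyltransferase complex. The share of kidney cells that lost Mettl3 was not measured here. Per its title, the study asked whether Mettl3 and m6A act on transcripts that promote cyst formation in mouse models of autosomal dominant polycystic kidney disease. The authors' deposited table lists 133 genes in 3 comparisons between the genotypes, each with 2 m6A libraries per genotype from 1 female and 1 male. Of these genes, 124 are annotated as protein coding, 7 as long non-coding RNAs and 2 as microRNAs, and they lie on 20 chromosomes. Log2 differences, p-values and FDR values below are those of the authors' deposited table, which gives no standard error and no value per replicate. Neither target of the mutations appears among the 133: Pkd1 (chromosome 17, 24548689 to 24596514, GRCm38) and Mettl3 (chromosome 14, 52294841 to 52308741) have no row, so the genotypes could not be checked from the table.

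The first comparison, SKO against WT, gives the change in m6A signal in the Pkd1 mutant kidney. In all 3 comparisons such a change can include a change in transcript level, since it is not given whether the input libraries entered. In the authors' deposited table, 105 of the 133 genes rose past an FDR of 0.05 and none fell, a direction that the making of the list fixed. The median log2 difference in the authors' deposited table was 2.14, with quartiles of 1.74 and 2.83, and the smallest was 1.29 for Map3k1. The largest rise in the authors' deposited table was that of Ddx18, an RNA helicase gene (chromosome 1, 121553835 to 121567980), at 12.1 with an FDR of 0.000502, although 28 genes had a smaller p-value. No signal level is given, so signal at or near 0 in WT cannot be excluded as the source of this size. Next in the authors' deposited table came Ifitm10 at 5.46 (chromosome 7, 142325835 to 142373779; FDR 4.17e-12), the smallest FDR of this comparison. Cldn6, a tight junction claudin, rose by 5.02 and Trpv6, an epithelial calcium channel, by 4.89 in the authors' deposited table. Further down the authors' deposited table, the non-coding transcript 4833417C18Rik rose by 4.57, Wnt7a, a secreted Wnt ligand, by 4.46, and Fam167a by 4.27. Ostc, a subunit of the oligosaccharyltransferase complex, rose by 4.21, the co-chaperone gene Dnaja2 by 4.08 and Dnaaf1, an assembly factor of ciliary dynein arms, by 3.92 in the authors' deposited table. FDR values of these 8 genes from Cldn6 to Dnaaf1 ran from 4.44e-08 for Trpv6 to 0.000695 for Ostc in the authors' deposited table.

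The Mettl3 knockout in the mutant background was addressed by DKO against SKO. In the authors' deposited table, 107 of the 133 genes fell past an FDR of 0.05 and none rose, again a direction fixed by selection. The median log2 difference in the authors' deposited table was -1.75, with quartiles of -2.34 and -1.51, and the value nearest 0 was -1.07 for Zfp523 (FDR 0.0857). Ddx18 fell by 12.48 (FDR 0.000403) in the authors' deposited table, a size that signal at or near 0 in DKO could likewise give. Degs2, a sphingolipid desaturase and hydroxylase gene (chromosome 12, 108686792 to 108702306), fell by 6.08 with an FDR of 4.35e-14, the smallest of this comparison in the authors' deposited table. Ust, a sulfotransferase acting on glycosaminoglycans, fell by 4.16 (FDR 1.24e-06) and Wnt7a fell by 3.69 (FDR 7.58e-05) in the authors' deposited table. The authors' deposited table then gives differences of -3.48 for the microRNA gene Mir101c (FDR 0.0435), -3.42 for Klhl31 (FDR 3.06e-05) and -3.26 for Arhgef28 (FDR 4.8e-05). Macc1 fell by 3.23, Nhlrc4 fell by 3.13 and Cyp4f17, a cytochrome P450 gene, fell by 3.07 in the authors' deposited table, with FDR values of 0.000291, 0.000206 and 0.00134. No peak here is assigned to a transcript with certainty, because no peak position is given. Of the genes named in these 2 comparisons, Map3k1, Trpv6, 4833417C18Rik, Wnt7a, Dnaaf1, Degs2, Ust, Arhgef28 and Nhlrc4 also each overlap another annotated gene (Taf1c for Dnaaf1, Evl for Degs2, Pigq for Nhlrc4).

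Both changes passed an FDR of 0.05 in 85 of the 133 genes of the authors' deposited table. A further 20 passed in SKO against WT alone, 22 in DKO against SKO alone, and 6 in neither. At an FDR of 0.01 the genes past both numbered 33 in the authors' deposited table. All 133 differences changed sign between the comparisons, which selection fixed; with 3 exchangeable groups and no selection a share of 66.7% would do so.

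The difference that was left between the double mutant and wildtype was given by DKO against WT. Selection limits it too: every DKO minus SKO value is -1.07 or lower in the authors' deposited table, so each DKO minus WT value lies below the SKO rise of the same gene. Of the 133 genes in the authors' deposited table, 6 differed past an FDR of 0.05, of which 5 were higher and 1 was lower in DKO, and 21 had an unadjusted p below 0.05. Ifitm10 stayed 4.12 above WT on the log2 scale (FDR 4e-06) and Trpv6 3.01 above (FDR 0.00589) in the authors' deposited table. Scara3, a scavenger receptor gene that overlaps a predicted gene, was 1.95 higher (FDR 0.0217), Hp, which encodes the plasma haemoglobin-binding protein haptoglobin, 1.72 higher (FDR 0.0427) and Egr1 1.5 higher (FDR 0.0298) in the authors' deposited table. Degs2 was the gene that fell below WT, with a log2 difference of -3.40 and an FDR of 0.00819 in the authors' deposited table. An FDR above the threshold does not show that a gene returned to its WT level, and with 2 libraries per genotype and no standard errors the table does not bound the remaining difference.

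Over all 133 genes of the authors' deposited table the median DKO minus WT difference was 0.38, with quartiles of -0.07 and 0.79. DKO lay above WT in 95 genes, below it in 37 and level with it in 1. Taking log2 as the scale, 49 genes were more than 1.5-fold above WT, 13 were more than 1.5-fold below, and 71 lay within 1.5-fold. As a share of each gene's SKO rise on the log scale, which does not depend on the base, a median of 16.6% was left in DKO, with quartiles of -3.22% and 33.6%, computed from the authors' deposited table. In 132 of the 133 genes DKO was closer to WT than SKO was, and Degs2 was the exception. Because every listed gene was selected for a DKO value below its SKO value, this count and the share left are partly set by the selection and do not measure how often loss of Mettl3 returns a gene towards WT. They are descriptions across genes of the same 6 m6A libraries, and genes are not replicates.

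**Figure D1:**
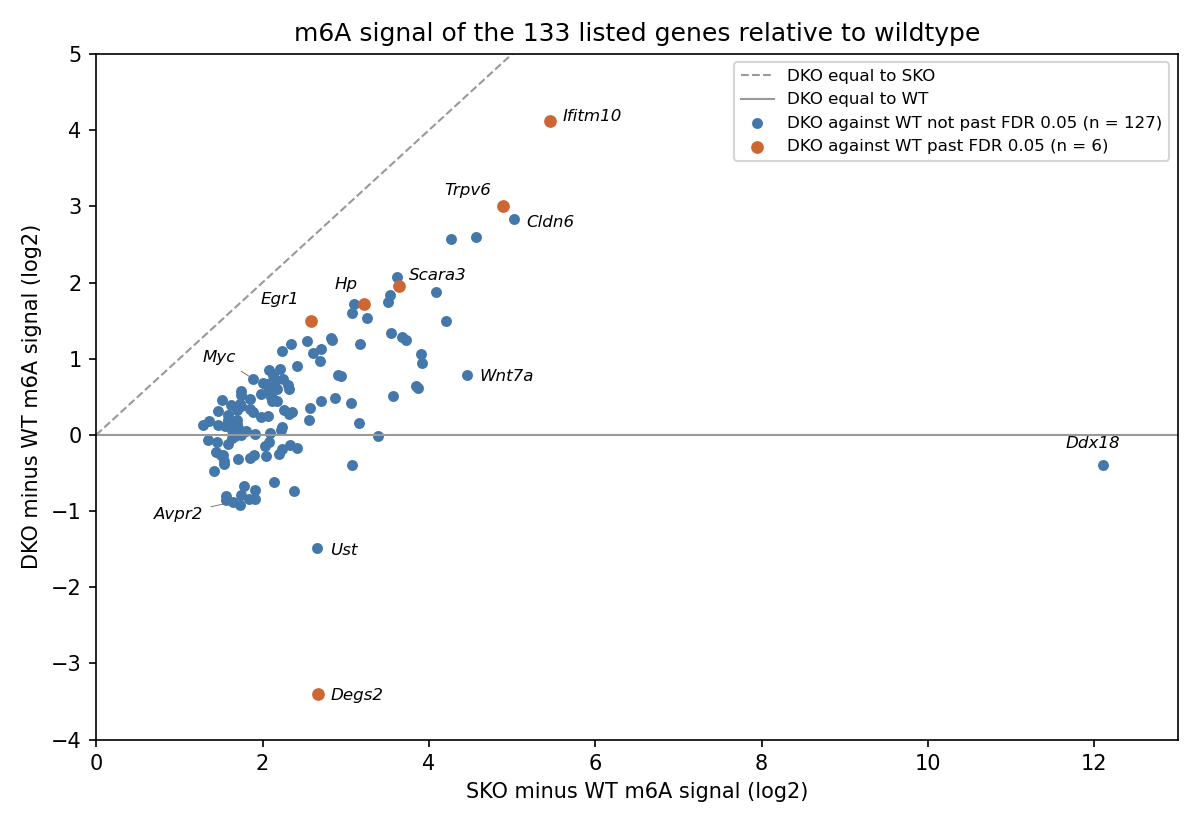
Each point is 1 of the 133 listed genes, with the SKO minus WT difference in m6A signal on the x axis and the DKO minus WT difference on the y axis, both log2 values of the authors' deposited table. Within 1.5-fold of the horizontal line where DKO equals WT lie 71 points, with 49 further above it and 13 further below. The 6 genes past an FDR of 0.05 in DKO against WT are in orange, and Ddx18 stands apart at 12.1.

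The collecting duct, the nephron segment in which vasopressin controls water reabsorption, was represented by 4 of 9 fixed marker genes of its principal cells. Aqp2, the water channel inserted on vasopressin signalling (chromosome 15, 99579056 to 99584545), rose by 1.69 in SKO (FDR 0.0302) and fell by 1.57 in DKO against SKO (FDR 0.0107) in the authors' deposited table. Avpr2, the vasopressin receptor of these cells (chromosome X, 73891765 to 73894428), had a SKO minus WT difference of 1.64 with an FDR of 0.0661, past 0.1 but not 0.05, in the authors' deposited table. It fell by 2.53 in DKO against SKO (FDR 6.28e-05), to a DKO minus WT value of -0.88 (FDR 0.477) in the authors' deposited table. The sodium channel subunit genes Scnn1b and Scnn1g rose by 1.98 (FDR 0.00357) and 1.78 (FDR 0.00573) in SKO in the authors' deposited table. Scnn1g fell by 2.47 in DKO against SKO (FDR 0.000407), and Scnn1b had a difference of -1.46 (FDR 0.0799) in the authors' deposited table. An FDR of 0.05 was passed by 3 of the 4 markers in each of the selected comparisons, but only Aqp2 and Scnn1g passed in both. In DKO against WT 0 of 4 did so, and none had an unadjusted p below 0.05 in the authors' deposited table. Over the whole list, 105 and 107 of the 133 genes passed in the selected comparisons and 6 in DKO against WT. The markers' counts are near these shares and do not set them apart from the rest of the list. Aqp2 and Avpr2 were also the 2 members found among 22 genes of the vasopressin and cAMP list. In the annotation Avpr2 overlaps Arhgap4, and Aqp2 and Scnn1g each overlap a predicted gene.

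No gene of the other fixed marker lists had a row. These held 13 proximal tubule, 9 thick limb and distal tubule, 5 intercalated cell, 5 podocyte, 6 endothelial, 7 fibroblast and mural, 9 immune and 4 erythroid markers, and genes of the table outside these lists can mark some of the same cell types. Absence from a selected list does not show that a gene's m6A signal was unchanged.

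Among 22 genes of the Myc and cell cycle list, 3 had a row, and all 3 rose in SKO, a direction fixed by selection. Myc, a transcription factor that drives cell growth (chromosome 15, 61985341 to 61990361), rose by 1.88 (FDR 0.00514) and fell by 1.16 in DKO against SKO (FDR 0.0492) in the authors' deposited table. Its DKO minus WT difference was 0.74 with an FDR of 0.493 in the authors' deposited table. The immediate-early genes Fos and Egr1, which cells switch on within minutes of a growth or stress stimulus, rose by 3.53 (FDR 4.7e-05) and 2.58 (FDR 2.24e-05) in SKO in the authors' deposited table. Fos fell by 1.72 in DKO against SKO (FDR 0.0183), whereas Egr1 had a difference of -1.09 with an FDR of 0.0683, in the authors' deposited table. Fos lay 1.83 above WT in DKO with an FDR of 0.084 in the authors' deposited table, so the list's 1 gene past the threshold in DKO against WT was Egr1. No cyclin, cyclin-dependent kinase or proliferation marker of the list had a row. Listed genes outside this fixed list can act in the cell cycle, as does Cdkn2b, a cyclin-dependent kinase inhibitor gene.

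The kidney injury and dedifferentiation list held 19 genes. Of these, Cd24a, a cell surface glycoprotein gene, had a SKO minus WT difference of 1.52 (FDR 0.0634) and fell by 1.80 in DKO against SKO (FDR 0.00269) in the authors' deposited table. None of the genes fixed for the other 6 lists was in the table. They were m6A writers, erasers and readers (21 genes), the methionine cycle (13), cystic disease and cilium (21), extracellular matrix and fibrosis (22), Hippo, Wnt and mTOR (21) and mitochondrial and lipid oxidation (15). Genes outside these lists can belong to the same themes, as do the Wnt ligand gene Wnt7a and the ciliary gene Dnaaf1 named above. Because only the selected rows were analysed here and the tested peaks were not, the pathway lists were not tested for enrichment, and whether m6A signal or transcript level changed cannot be separated without the input libraries.

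**Figure D2:**
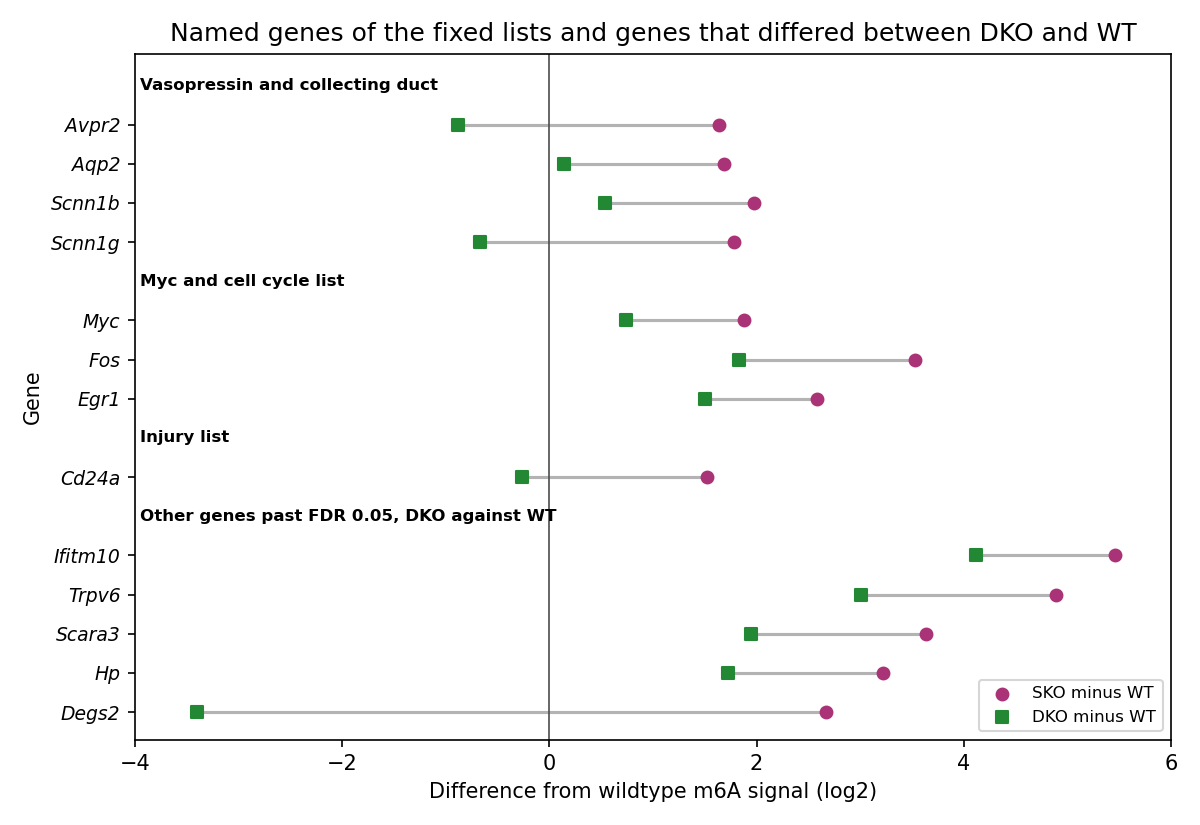
For each gene the circle gives SKO minus WT and the square DKO minus WT, log2 differences of the authors' deposited table, joined by a line. The 4 collecting duct markers lie between 1.64 and 1.98 in SKO and between -0.88 and 0.54 in DKO, and Degs2 crosses from 2.67 to -3.40.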

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

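Directions did not change under any alternative that the table allowed, which for SKO against WT and DKO against SKO follows from how the list was selected. The counts depended on the FDR limit. At an FDR of 0.01, 64 genes passed in SKO against WT, 54 in DKO against SKO and 3 in DKO against WT. The other alternatives that moved a value were chosen after seeing the data. Genes past both selected comparisons numbered 33 at an FDR of 0.01 and 133 at 0.1, the latter fixed by selection. DKO against WT gave 10 genes at 0.1. Keeping only the 85 genes past 0.05 in both moved the median SKO minus WT difference from 2.14 to 2.32. The other 25 of 32 alternatives left their value within 1.5 times for a count, or within its binomial interval across genes for a median or share. Of these, 9 could not move anything, because the minimum changes and the use of 1 row per gene took no gene out of the list in the selected comparisons, and they say nothing about stability. The counts at an FDR of 0.1 in SKO against WT and in DKO against SKO were also fixed by selection, at 133. The same holds for the pathway list members at that limit. Leaving out Ddx18 took 1 gene from 133, so a median or share could barely move. Not run, because the table holds no values per library, signal levels or peak positions, were other normalizations, pseudocounts, scalings and tools, fits to 2 genotypes only, the filter on low values, leaving out each replicate, separate SKO libraries for each difference, and other annotation classes. No paired analysis was possible because the table has no replicate columns. Depth is unknown, and with 2 libraries per genotype the stability of single calls was not tested.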

Other observations

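Every test in this part was chosen after the data were seen. Genes named in the next paragraph fall outside the rule for named genes and were chosen after their values were seen.

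The genes below are single examples, their directions were fixed by the selection of the list, and no shared function was tested. Edn1, which encodes the peptide endothelin 1, rose by 2.57 in SKO (FDR 0.00349) and fell by 2.23 in DKO against SKO (FDR 0.00935) in the authors' deposited table. Btc and Hbegf encode ligands of the epidermal growth factor receptor; Btc rose by 3.51 (FDR 0.000458) and Hbegf by 1.55 (FDR 0.0335), and they fell by 1.77 (FDR 0.0244) and 1.44 (FDR 0.0184) in DKO against SKO in the authors' deposited table. Gdf15, a stress-induced cytokine gene, rose by 2.04 (FDR 0.00406) and fell by 2.34 (FDR 0.0164), and Agtr1a, the type 1a angiotensin II receptor, rose by 2.07 (FDR 0.00374) and fell by 1.83 (FDR 0.00363) in the authors' deposited table. Cd14, a co-receptor for bacterial lipopolysaccharide, rose by 2.83 (FDR 2.24e-05) and fell by 1.61 (FDR 0.00636) in the authors' deposited table. The claudin gene Cldn4 rose by 2.33 (FDR 0.000234) and fell by 2.48 (FDR 6.99e-06) in the authors' deposited table. Muc1, an apical mucin, rose by 1.69 (FDR 0.0214) and fell by 1.52 (FDR 0.0181) in the authors' deposited table. A fall against SKO is not a return to WT, and the difference left varied. DKO minus WT was 1.75 for Btc, 1.24 for Cd14, 0.35 for Edn1 and 0.25 for Agtr1a in the authors' deposited table. It was 0.19 for Muc1, 0.12 for Hbegf, -0.13 for Cldn4 and -0.28 for Gdf15.

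The list is a small part of what the authors tested. If the FDR values are Benjamini-Hochberg values, at least 26113 peaks or regions were tested. At least 1913 of them reached an FDR of 0.0924 or less in SKO against WT, at least 1182 reached 0.0994 or less in DKO against SKO, and at least 1116 reached 0.084 or less in DKO against WT, in either direction. How those sites divide between rises and falls cannot be read from these values.

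The first pattern is the number of genes higher in SKO than in WT and lower in DKO than in SKO. Both differences hold the same SKO libraries, so a few such genes arise with no effect at all. In 1000 simulated sets of 26113 unchanged features, with the p limits of the list, the mean was 5.72 and the highest count was 14. The list holds 133 genes. If the p-values are calibrated, this argues only against a table in which no feature changed, and the least counts above already spoke against such a table. Real effects in either comparison, combined with noise of the shared SKO libraries, were not simulated. The simulation therefore does not decide how many listed genes arose in that way. The value of 26113 is the least number of tests, and the simulated count grows in proportion to it. Independent lists of the least sizes above would share 86.6 features in any direction, a value that leaves out the shared libraries, and the excess over it is not read as a shared effect. A property of the SKO libraries alone, such as handling or precipitation, cannot be told apart from a return towards the WT level, because the table holds no value per library, and the 10 genes past an FDR of 0.1 between DKO and WT do not decide, since that comparison shares the WT libraries with the one that chose the list. The labels name no genotype with loss of Mettl3 alone. A fall that this loss would give in any background therefore cannot be told apart from a reversal of the Pkd1 effect.

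The second pattern is the presence of 4 of 9 collecting duct markers against 0 of 58 genes of the other fixed marker lists. A two-sided Fisher's exact test gave p = 0.000164, or 0.00148 adjusted over the 9 marker lists. Avpr2 was known from the study, and without it (3 of 8 markers) a two-sided Fisher's exact test gave p = 0.00122, not adjusted over the lists. The value to set beside it is the unadjusted 0.000164. Fisher's exact test treats markers as independent, but all were measured in the same libraries, and markers of the same cell type can move together. The p-values can therefore overstate the evidence against equal entry of all marker lists. Markers without a called peak could not have entered, and listed genes outside the fixed lists, such as Cd14, can mark other cell types. A candidate explanation is 1 factor common to all collecting duct transcripts, such as a larger share of these cells in the cystic kidney, rather than a change in methylation of each transcript. In SKO against WT the 4 log2 differences spanned 0.34, a range matched or undercut by 1.76% of 10000 random sets of 4 listed genes. All 4 lay below the list's median of 2.14, whereas random sets were drawn from values of 1.29 to 12.1. The small range may therefore reflect small rises and does not decide. In DKO against SKO the 4 differences spanned 1.07, a range matched or undercut by 42.1% of random sets. Both explanations stay open. No errors of the folds are given that would tell a common factor from separate changes. The input libraries that would give the transcript levels were not analysed here.

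The third pattern is the Ddx18 difference of 12.1 in the authors' deposited table, where the next largest SKO minus WT value is 5.46. The size may come from signal at or near 0 in WT and DKO, in which case it depends on the floor and gives no measured fold. Its p-value is not the smallest, since 28 listed genes have a smaller p in SKO against WT and 15 in DKO against SKO, but this was known when the gene was picked and does not decide. In the authors' deposited table Ddx18 and Mir101c are the 2 genes with an identical DKO minus WT difference and p (-0.39 and p = 0.898), which peaks at the same floor in WT and DKO could have. A difference in methylation or expression of Ddx18 in SKO was not tested, and the table analysed here holds no signal level that would decide its size.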
